A study of Homo sapiens with 4 samples.

How the data were processed

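Blood monocytes from healthy volunteers were cultured for 6 h in medium with 20% autologous serum, alone or with 1000 U/ml of recombinant interferon alpha-2b (IFN-α2b), and total RNA was hybridised to Affymetrix expression arrays, per the labels' protocols. RNA was isolated with 1 of 2 kits according to the cell yield, per the labels, which do not say which kit a sample had. RNA was amplified and biotin-labelled with a two-cycle kit, a procedure that copies the 3' end of transcripts preferentially. The series holds 4 arrays in 2 tables. Each table holds 1 array type with 1 serum-alone array and 1 IFN-α2b array. The 2 designs are the first and second array of one Affymetrix human expression set, called array type A and array type B here after the last letter of the sample titles. The titles' A and B therefore name the array type, not a replicate, and each of the 4 groups has 1 array. The labels do not say how many volunteers gave cells, whether RNA was pooled, or whether the A and B arrays of a condition share RNA.

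The values deposited by the authors are intensities, 1 linear signal per probe set, never negative and written with 1 decimal. The signal algorithm, its software and its scaling are not given in the sources used here. On each array the mean signal lay between 499.88 and 499.98 after trimming 2% of the probe sets at each end, which is the form of a signal scaled to a fixed target. Scale (linear), centring (none across genes) and direction (signal per array, no ratio) are thus known from the values, and the algorithm and background correction are not. Array type A had 22283 probe sets and type B 22645, each with 68 control probe sets. No column was left without a sample. Detection calls were not used here. A probe set named 1 gene for 19065 of the 22215 non-control probe sets of type A (1043 named several and 2107 none) and for 15426 of the 22577 of type B (554 named several and 6597 none). Names came from the platform annotation, checked by Entrez identifier against the RefSeq gene table of GRCh38.p14, which changed 0 symbols. A probe set with several names or none was left out of gene counts, so a listed gene can be unmeasured here because its probe sets are unnamed. Y-linked genes and XIST were left out.

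All comparisons set the IFN-α2b array against the serum-alone array of the same type. The choices of this paragraph were made before the data were examined. The deposited scale was to be kept if the median log2 ratio over the brighter 50% of the probe sets lay within 0.2 of 0, and it was -0.03 on both types. A floor was set at the 50th percentile of all non-control signals of the array type, 151 on type A and 230.4 on type B. A probe set counted as measured if at least 1 of its 2 signals lay above the floor. A signal below the floor was set to it, and the ratio is then written as "at least". A gene took its brightest measured probe set. This gave 7868 measured genes on type A and 6746 on type B. With 1 array per group there was no test, no standard error and no p-value. Genes were counted by size, at least 2-fold higher or lower. The 25 gene lists were fixed beforehand, and the median log2 ratio of each list with at least 3 measured genes was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins per array type. That percentile describes these arrays and is not a p-value. A gene measured on both types entered its list with the type A value. The genes named are the 15 highest and 10 lowest log2 ratios of type A and the 10 highest and 5 lowest of type B, on both types only where a gene's measured probe sets all differed in one direction, and the 2 highest and 2 lowest members of each list. Others are said to have been chosen after their values were seen.

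Repeat measurement was described from the 100 probe sets that both array types carry. Their log2 ratios differed between types with an SD of 0.60, or 0.42 for a single ratio if both types err alike. The counting was tested on simulated data made from the serum-alone signals with that SD as noise and 200 probe sets changed. For array type A, 45 of 50 genes raised 3-fold and 39 of 42 lowered 3-fold were counted as at least 2-fold changed over 7182 genes, and 56 and 40 of 7004 unchanged genes were counted as higher and lower. For array type B, the counts were 44 of 50 and 40 of 43 over 6092 genes, and 49 and 37 of 5915. The noise SD came from probe sets mostly far above the floor, and the same SD served both types. Over those 100 probe sets, however, the log2 ratios had an SD of 0.63 on type A and 0.44 on type B. At least 2-fold lower were 11 of them on type A and 0 on type B. The simulation therefore cannot show how often unchanged genes are counted when they are dim, or on type A. The random-list procedure put 187 of 200 random lists of 15 genes inside the range without the outer 2.5% at each end. Alternatives covered the scaling, the floor, the fold threshold, the probe set chosen for a gene and the array type used for a list. Scaling on bacterial hybridization controls was added after seeing the data. The number of arrays limits the precision. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.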

Results

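Transcript levels were measured in human blood monocytes, the circulating precursors of macrophages and of some dendritic cells, after 6 h in 20% autologous serum with or without 1000 U/ml of IFN-α2b, a type I interferon. The series title places the comparison in a study of transcripts induced by serum from patients with systemic lupus erythematosus, and the question addressed by these arrays was which monocyte transcripts IFN-α2b itself alters. Cells exposed to patient serum are not analysed here. Each condition was read once on array type A and once on array type B, 4 arrays in all, so no value below has a replicate or a standard error. Median signals over all probe sets were 135 with serum alone and 165.9 with IFN-α2b on type A, and 225.6 and 235 on type B. For the 100 probe sets present on both types, the log2 ratios of the types differed with an SD of 0.60, and had an SD of 0.63 over the probe sets on type A and 0.44 on type B. The 3' to 5' signal ratio of the GAPDH control, a measure of transcript truncation, was 3.75 with serum alone and 6.16 with IFN-α2b on type A, and 4.43 and 6.14 on type B. That of beta-actin was 11.2 and 13.8 on type A, and 10.9 and 19.5 on type B.

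The highest ratios belonged to antiviral effectors and chemokines. On array type A, CXCL10, a chemokine that attracts activated T cells, was 161-fold higher with IFN-α2b, with a signal of 387.2 in serum alone and 62409 with IFN-α2b. RSAD2 (viperin, an antiviral radical-SAM enzyme) was 120.3-fold higher and ISG15, a ubiquitin-like modifier, 90.5-fold higher. IFIT1, which binds viral RNA, was at least 88.6-fold higher, because its serum-alone signal of 143.4 lay below the floor. The monocyte-attracting chemokine CCL8 was at least 58.2-fold higher. HERC5, the ligase that attaches ISG15, was 37.2-fold higher, its relative HERC6 32.1-fold and IFIT2 29.5-fold. The RNA helicase DHX58 was at least 29.1-fold higher and USP18, which removes ISG15 and restrains interferon signalling, at least 26.9-fold. IFI44L was 27.8-fold higher, IDO1 (the enzyme that degrades tryptophan) 26.8-fold, GBP1 25.4-fold, TNFSF10 (TRAIL, a death ligand) 25.1-fold and IFITM1, which hinders viral entry, 25.1-fold.

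On array type B the order began with RSAD2, 78.5-fold higher, and IFIT2, 60.6-fold higher, both read by probe sets other than those of type A. NEXN, which encodes an actin-binding protein, was at least 54.3-fold higher, with a signal of 25.1 in serum alone and 12508 with IFN-α2b. IFIT3 was 50.2-fold higher on type B and had a log2 ratio of 3.28 on type A. SAMD9L was 41.0-fold higher, PNPT1 (a mitochondrial RNA-degrading enzyme) 40.4-fold, GBP5 29.5-fold, GBP1 29.2-fold (log2 ratio 1.73 by its other type B probe set), NCOA7 25.8-fold and GBP3 23.5-fold.

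**Figure D1:**
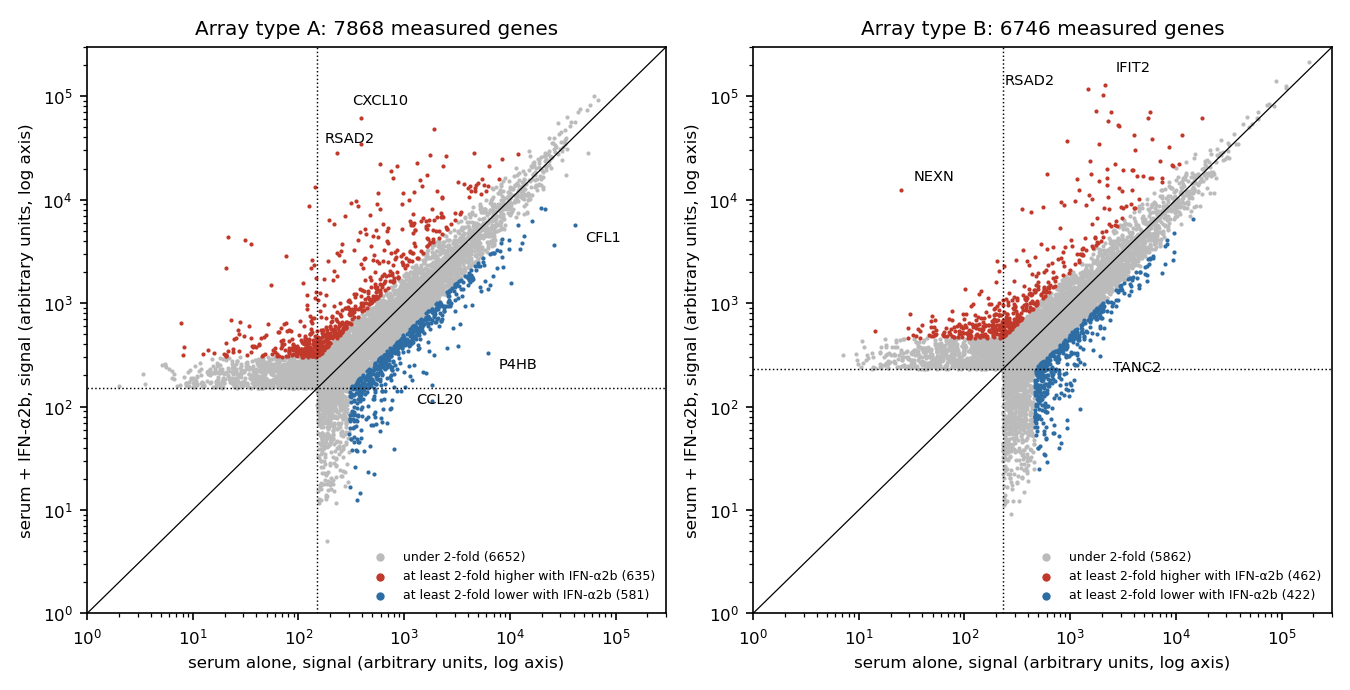
Signal of each measured gene with serum alone (horizontal axis) and with serum plus IFN-α2b (vertical axis) on array type A (left) and B (right), in arbitrary units on log axes. Dotted lines mark the floor of 151 on type A and 230.4 on type B, the solid line marks equal signals, and red and blue points are genes at least 2-fold higher or lower. Genes higher with IFN-α2b reach ratios over 100, such as CXCL10 at 161-fold, while the lowest gene, P4HB, lies 18.8-fold below.

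In all, 635 of 7868 measured genes on array type A were at least 2-fold higher with IFN-α2b and 581 at least 2-fold lower, and 462 and 422 of 6746 on type B. Higher genes outnumbered lower ones by more at larger sizes. At 4-fold or more, 119 genes were higher and 41 lower on type A, and 71 and 18 on type B. At 16-fold or more, the counts were 24 and 1 on type A and 14 and 0 on type B. Bacterial control transcripts, which are added to the labelled sample in a fixed amount, had a median log2 ratio of 0.38 on type A and 0.53 on type B. When each pair of arrays was scaled on these controls, 342 genes were at least 2-fold higher and 1290 lower on type A, and 201 and 1434 on type B. The share of 2-fold differences that were higher was then 21.0% on type A and 12.3% on type B, against 52.2% and 52.3% on the deposited scale. That scaling places the median log2 ratio of all genes at -0.33 on type A and -0.51 on type B, and ratios are given relative to the bulk of transcripts.

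Of 54 antiviral interferon-stimulated genes listed beforehand, 53 were measured and 52 were at least 2-fold higher, with a median log2 ratio of 3.57 (11.9-fold), above all 10000 random lists. The smallest difference among those 52 was that of DDX60L, a helicase-like gene, at 2.75-fold. Scaled on hybridization controls, 51 were at least 2-fold higher and DDX60L had a log2 ratio of 0.93. TRIM5, a restriction factor for retroviruses, had a log2 ratio of 0.23 on type A and at least 1.77 on type B (-0.15 on type A when scaled on hybridization controls). All 7 measured interferon-inducible chemokines were at least 2-fold higher, with a median log2 ratio of 3.36. The smallest was that of CCL5 at 2.09-fold (log2 ratio 0.68 when scaled on hybridization controls, which left 6 of 7 at 2-fold), and CXCL9 was at least 4.24-fold higher. Of 14 measured guanylate-binding proteins and other genes associated with interferon gamma, 13 were at least 2-fold higher (median log2 ratio 2.85, above all random lists). GBP5 and IDO1 had the highest values, SECTM1 was 2.27-fold higher (log2 ratio 0.80 when scaled on hybridization controls), and the adhesion molecule ICAM1 had a log2 ratio of 0.40 by its brightest probe set and from -1.47 to 0.61 over its 3.

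Interferon signalling genes differed less. Of 20 measured members, 6 were at least 2-fold higher and 0 lower, and the median log2 ratio was 0.49, at percentile 99.94 of random lists (median 0.12, with 4 higher and 1 lower, when scaled on hybridization controls). The transcription factor IRF7, an amplifier of interferon production, was 9.30-fold higher and the kinase JAK2 3.66-fold. The receptor subunit IFNAR2 and the kinase TYK2 had log2 ratios of -0.64 and -0.61. Nucleic acid sensors and Toll-like receptors had a median log2 ratio of 0.67 (percentile 99.97), with 6 of 15 at least 2-fold higher and 1 lower. That median was 0.24 when scaled on hybridization controls and 1.17 with the 25th percentile floor. The DNA sensors AIM2 and IFI16 were 13.0-fold and 5.98-fold higher, with log2 ratios of IFI16 from 0.93 to 2.58 over its 3 probe sets. TLR5, the flagellin receptor, was 2.56-fold lower, and STING1 had a log2 ratio of -0.27.

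The MHC class I pathway had a median log2 ratio of 0.84, above all random lists, and 6 of its 17 measured genes were at least 2-fold higher. NLRC5, the transactivator of class I genes, was 5.04-fold higher and the immunoproteasome subunit PSMB9 3.71-fold. HLA-G had a log2 ratio of -0.01 (up to 0.40 over its 4 probe sets) and the peptidase ERAP2 one of 0.14 or more. Probe sets of the classical and non-classical HLA genes can read one another's transcripts. None of the 12 measured MHC class II pathway genes differed by 2-fold by the value used for the list (0 higher, 0 lower, median log2 ratio 0.35, percentile 94.9; median -0.03 when scaled on hybridization controls). In that list CTSS, a lysosomal protease, had a log2 ratio of 0.85 (-0.14 by its other probe set), HLA-DPB1 0.61 (signals of 313.5 and 626.2 by another probe set on type B) and the class II transactivator CIITA -0.32 (0.54 by its other probe set). HLA-DOA lay below the floor with IFN-α2b on type A, with a log2 ratio of -0.48 or less, and had 0.005 on type B.

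Genes of dendritic cell maturation and migration had a median log2 ratio of 1.19, above all random lists, with 8 of 15 at least 2-fold higher and 1 lower. IL15RA, which presents interleukin-15, was 13.2-fold higher and TNFSF13B (BAFF, a B cell survival factor) 10.6-fold. CCR7, the receptor that guides dendritic cells to lymph nodes, was 2.79-fold higher, and was chosen after its value was seen. The chemokine CCL22 was at least 3.42-fold lower, and CCL19 was at least 1.08-fold higher. Without probe sets shared between transcripts, the list's median log2 ratio was 0.70 over 11 genes. On the deposited scale all 14 measured cell death genes had log2 ratios above 0 by the value used for the list, and 5 were at least 2-fold higher (median log2 ratio 0.82, percentile 99.99). Beside TNFSF10, the death receptor FAS was 2.89-fold higher on type A (log2 ratios from 0.10 to 1.53 over its 4 probe sets) and had a log2 ratio of 0.17 on type B. MCL1 and BID, an anti-apoptotic and a pro-apoptotic member of the BCL2 family, had log2 ratios of 0.19 and 0.12 (-0.19 and -0.26 when scaled on hybridization controls). BID had -1.68 by its other probe set, and the 5 probe sets of MCL1 ranged from -0.19 to 0.79. On type B, MCL1 had -0.43 and BID 0.006. Scaled on hybridization controls, 2 of the 14 were at least 2-fold higher. With the median over probe sets, 2 of 14 were so as well (percentile 99.83 for the list median). Without shared probe sets, 2 of 12 were higher and 1 was lower (percentile 99.35).

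Inflammatory NF-kB targets went both ways. Of 17 measured, 3 were at least 2-fold higher and 3 lower, with a median log2 ratio of 0.29 at percentile 94.5 (-0.06 when scaled on hybridization controls and -0.08 without shared probe sets). The interleukin-1 receptor antagonist IL1RN was 15.4-fold higher (log2 ratios from 1.38 to 3.95 over its 3 probe sets) and IL6 4.85-fold, while the chemokines CCL20 and CXCL2 were 6.64-fold and 2.85-fold lower. CXCL2 had a log2 ratio of -0.28 or less on type B. The remaining 2, chosen after their values were seen, were TNFAIP6 (3.39-fold higher) and CXCL1 (2.57-fold lower). All 6 measured metallothioneins, small metal-binding proteins, were at least 2-fold higher, with a median log2 ratio of 2.27, above all random lists. MT1G was 9.76-fold higher, MT1H 6.15-fold, MT1E 2.08-fold and MT1F 2.03-fold. Scaled on hybridization controls, 4 of the 6 were at least 2-fold higher, and MT1E and MT1F had log2 ratios of 0.67 and 0.64. Their sequences are near-identical, so the members cannot be told apart with confidence.

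**Figure D2:**
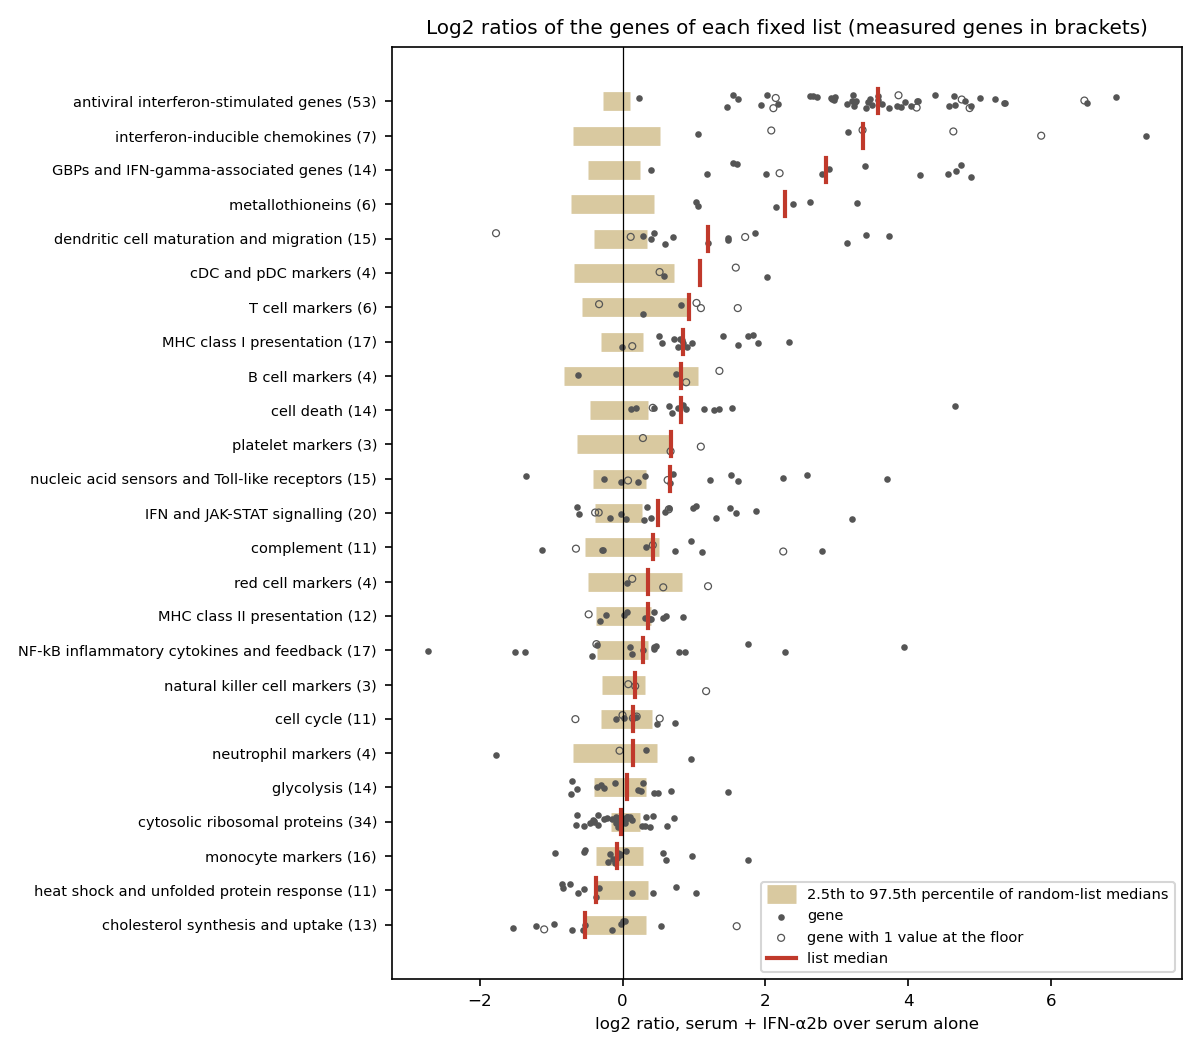
Log2 ratio of each measured gene of the 25 fixed lists (points, horizontal axis, positive when higher with IFN-α2b; open points have 1 signal at the floor), with the list median as a red bar and the range of random-list medians without the outer 2.5% at each end in tan. GBPs are guanylate-binding proteins, and cDC and pDC are conventional and plasmacytoid dendritic cells. The medians of the antiviral genes (3.57), chemokines (3.36) and metallothioneins (2.27) lie to the right of their random ranges, and those of ribosomal proteins (-0.03, from -0.41 to 0.003 over the settings named in the text) and monocyte markers (-0.07, from -0.45 to 0.07) lie inside.

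Monocyte markers had a median log2 ratio of -0.07 (percentile 48.4; 0.07 with loess correction), with 1 of 16 at least 2-fold higher and 0 lower (median -0.45, with 1 higher and 1 lower, when scaled on hybridization controls). The chemokine receptor CCR1 was 3.38-fold higher and the haemoglobin scavenger receptor CD163 had a log2 ratio of 0.97. The growth factor receptor CSF1R and the fractalkine receptor CX3CR1 had log2 ratios of -0.55 and -0.94. Cytosolic ribosomal proteins had a median log2 ratio of -0.03 (percentile 29.4; 0.003 with median centring), with 0 of 34 at least 2-fold different (median -0.41, with 2 lower, when scaled on hybridization controls). RPLP2 and RPS16 were highest at 0.72 and 0.62, and RPL29 and RPS19 lowest at -0.65 and -0.64, but other probe sets of RPS16 and RPL29 had -0.08 and 0.18. RPLP2 was read near the floor of 151, with signals of 213 in serum alone and 351.4 with IFN-α2b. The list's median signals were 16113.5 and 14259. On type B, RPS19 had a log2 ratio of -0.05. Glycolysis genes had a median of 0.06 (percentile 75.5; -0.32, with 3 of 14 at least 2-fold lower, when scaled on hybridization controls). Hexokinase HK2 was 2.79-fold higher, PKM had a log2 ratio of 0.68, and PGAM1 and the glucose transporter SLC2A1 had -0.72 each. Cell cycle genes had a median of 0.15 (percentile 68.5; -0.21 when scaled on hybridization controls) and 0 of 11 differed by 2-fold. PCNA had a log2 ratio of 0.73, CCNA2 one of 0.52 or more, MCM2 -0.09 and MCM4 -0.66 or less.

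Cholesterol genes had a median log2 ratio of -0.53 at percentile 2.56, with 3 of 13 at least 2-fold lower and 1 higher (median -0.91, with 5 lower and 1 higher, when scaled on hybridization controls). Without shared probe sets the median was -0.15 over 11 genes, at percentile 45.3, with 1 lower and 1 higher. With the median over probe sets it was -0.34, at percentile 13.3. SQLE, an enzyme of sterol synthesis, was 2.89-fold lower and the sterol exporter ABCG1 2.31-fold by its brightest probe set (log2 ratio 0.52 by its other one). CH25H, which makes 25-hydroxycholesterol, was at least 3.03-fold higher, and LSS had a log2 ratio of 0.54. Heat shock and unfolded protein response genes had a median of -0.37 (percentile 3.65), with 1 of 11 at least 2-fold higher and 0 lower (median -0.75, with 0 higher and 3 lower, when scaled on hybridization controls). ATF3 was 2.04-fold higher (log2 ratio 0.65 when scaled on hybridization controls), HSP90AA1 had a log2 ratio of 0.75, and the chaperones HSP90B1 and DNAJB1 had -0.85 and -0.83 (DNAJB1 0.12 by its other probe set). Complement genes had a median of 0.42 (percentile 93.4), with 3 of 11 at least 2-fold higher and 1 lower (2 higher when scaled on hybridization controls). The C1 inhibitor SERPING1 was 6.94-fold higher and the receptor C5AR1 2.20-fold lower. CFB was at least 4.76-fold higher by its brighter probe set and had a log2 ratio of -0.10 by the other. C1QC had a log2 ratio of -0.65 or less on type B.

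Markers of other blood cells were read from few genes. Of 14 T cell markers 6 were measured, 4 of them with 1 signal below the floor (median log2 ratio 0.92, percentile 97.7). With no floor, the median over 13 was 0.43, at percentile 64.4. TRBC1 was at least 3.06-fold and LCK at least 2.14-fold higher, CD8A had a log2 ratio of 0.29 (-0.09 when scaled on hybridization controls) and CD5 one of -0.33 or less. Of 9 B cell markers 4 were measured (median 0.82, percentile 90.7). That median was 0.023 over 8 genes with no floor, at percentile 28.9, and 0.12 when scaled on hybridization controls. PAX5 was at least 2.56-fold higher, CD79A had a log2 ratio of 0.89 or more, TCL1A 0.74 and CD22 -0.63 (up to 1.16 over its 3 probe sets). The 3 measured natural killer cell markers, PRF1, KLRD1 and GZMB, had log2 ratios of at least 1.17, 0.18 and 0.08 (percentile 65.6 for the list median, against 96.6 for a median of 1.23 over 10 genes with no floor). The 3 measured platelet markers, ITGB3, TUBB1 and PPBP, had at least 1.10, 0.67 and 0.29 (percentile 98.4), all with serum-alone signals below the floor, and the 4 probe sets of ITGB3 went down to 0.02. The platelet list turned direction with the floor, to a median of -0.58 at percentile 10.6 with the 25th percentile floor, and to -1.05 at percentile 0.93 with no floor, where 4 of 7 were at least 2-fold lower. Red cell markers had a median of 0.35 (percentile 61.8), or 0.88 with no floor (percentile 89.5). CA1, AHSP and ALAS2 had log2 ratios of at least 1.20, 0.57 and 0.14, and HBB had 0.06 (ALAS2 -0.08 or less and HBB -0.32 when scaled on hybridization controls). Neutrophil markers had a median of 0.14 (percentile 85; -0.05 when scaled on hybridization controls), with FCGR3B at 0.96, CSF3R at 0.33, MMP8 at -0.04 or less and the gelatinase MMP9 at -1.77. Markers of conventional and plasmacytoid dendritic cells had a median of 1.08 (percentile 99.8) over 4 genes, or 0.55 over 7 with no floor (percentile 79.96). TCF4 was 4.08-fold (log2 ratios from 0.89 to 2.29 over its 7 probe sets) and IL3RA at least 3.00-fold higher, and CLEC10A and CD1C had log2 ratios of 0.58 and at least 0.52.

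The lowest ratios belonged to genes of mixed function. On array type A, P4HB, a disulfide isomerase, was 18.8-fold lower by its brightest probe set and had a log2 ratio of -0.56 by its other one. The signalling adaptor GAB2 was at least 12.2-fold lower, PRKCSH 11.4-fold (log2 ratio -0.11 by its other probe set), NAA50 8.30-fold, SMAD7, an inhibitor of TGF-beta signalling, 7.65-fold, and CFL1 (cofilin, an actin-severing protein) 7.28-fold. NACA4P was 7.15-fold lower, PALLD 6.96-fold (log2 ratio up to -1.004 over its 3 probe sets), the ubiquitin ligase SIAH1 6.92-fold and CCL20 6.64-fold. The probe sets used for PRKCSH, NACA4P and SIAH1 are of the kind that shares probes between genes, so other transcripts can contribute. On type B, where they were also measured, NAA50 had a log2 ratio of -0.75, SIAH1 one of -0.67 or less, and CFL1 had 0.65 with the same probe set. The lowest on array type B were TANC2 (6.22-fold lower), WIPI2 (at least 5.39-fold), VARS2 (5.20-fold), ADHFE1 (at least 4.71-fold) and YDJC (4.67-fold). WIPI2 had a log2 ratio of -0.75 on type A.

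The array types allowed a check of size and direction with other probe sets. Of 2161 genes measured on both types by different probe sets, 24 were at least 4-fold higher on type A. All 24 had a ratio above 0 on type B, and 22 were at least 2-fold higher there, against 7.82% of all 2161 genes. Of 13 genes at least 4-fold lower on type A, 11 had a ratio below 0 on type B and 3 were at least 2-fold lower there, against 6.11% of all genes. At 2-fold, 58 of 140 higher genes (41.4%) and 21 of 178 lower genes (11.8%) were at least 2-fold different in the same direction on type B. In direction, 115 of the 140 and 126 of the 178 agreed between types, while 53.9% of all 2161 genes were below 0 on type B. Starting from type B, 25 genes were at least 4-fold higher, of which 22 had a ratio above 0 on type A and 19 were at least 2-fold higher there, and 3 were at least 4-fold lower, of which 3 had a ratio below 0 on type A and 0 were at least 2-fold lower there. Of 169 genes at least 2-fold higher on type B, 34.3% were so on type A, as were 15.9% of 132 lower ones, against 6.48% and 8.24% of all genes, and 134 of the 169 and 81 of the 132 agreed in direction. Among the 100 probe sets present on both types, 11 were at least 2-fold lower on type A and 0 of all 100 were so on type B, while 1 of 2 at least 2-fold higher on type A was so on type B. Several probe sets of a gene on 1 type had opposed directions for 1056 of 2307 genes on type A and 933 of 1954 on type B.

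**Figure D3:**
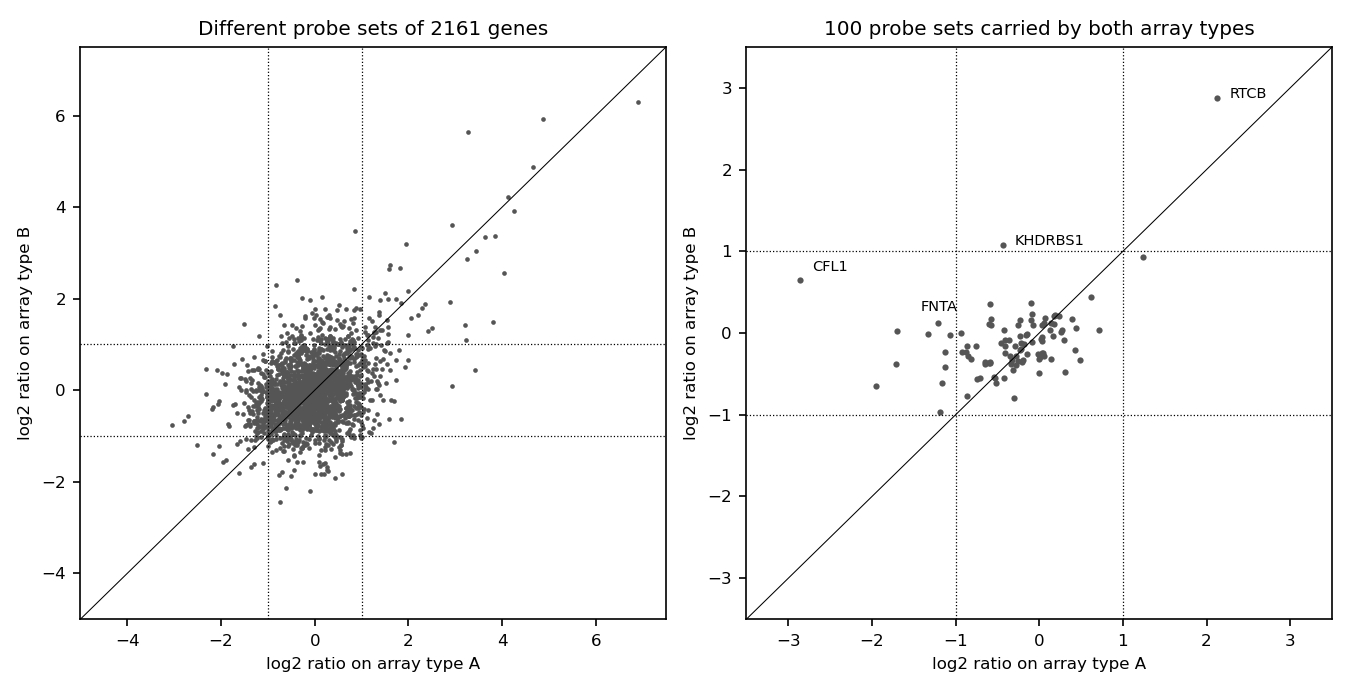
Log2 ratio of IFN-α2b over serum alone on array type A (horizontal axis) and type B (vertical axis), for 2161 genes read by different probe sets (left) and for the 100 probe sets carried by both types (right). The solid line marks equal ratios and dotted lines mark 2-fold. On the left, 22 of the 24 genes at least 4-fold higher on type A lie above the upper dotted line, and on the right CFL1 lies at -2.86 on type A and 0.65 on type B.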

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

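Apart from that of the hypoxia list in the last part, the tests of explanations in the closing section were chosen after the results were seen. Among named probe sets carried by both array types, 3 had ratios of opposite direction on the 2 types with at least 1 of them 2-fold or more. CFL1 had a log2 ratio of -2.86 on type A and 0.65 on type B, FNTA -1.21 and 0.12, and KHDRBS1 -0.44 and 1.07. With 1 array per condition and type, the difference was not tested. Without CFL1, the SD of the difference between types over the shared probe sets was 0.50 in place of 0.60. Control probe sets for 2 Bacillus transcripts, lys and thr, which no comparison above used, passed the floor in more probe sets with IFN-α2b than with serum alone. On type A, 1 of 6 passed for each, at 200.2 for lys and 175.7 for thr, against highest serum-alone signals of 57 and 76. On type B, 1 of 6 passed for lys, at 396.4 against 101.3, and 2 of 6 for thr, up to 517.2, against 1 of 6 with serum alone, at 239.2. For phe, 1 of 6 passed on both type B arrays, at 427 with IFN-α2b and 289.1 with serum alone.

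Genes at least 2-fold lower with IFN-α2b on array type A were seldom 2-fold lower on type B, though most had a ratio below 0 there. Different transcripts read by different probe sets cannot explain this for probe sets that are the same on both types. Among these, 11 shared probe sets were at least 2-fold lower on type A. Their median log2 ratio was -0.23 on type B, where 8 of them and 67 of all 100 shared probe sets lay below 0. The loss of size thus also occurred without a change of probe set. The 11 were picked for low type A values, however, and smaller differences on type B can arise from that choice. That check does not reach the 178 genes read by different probe sets, for which the explanation remains open. Error of the single type A arrays alone is argued against only weakly. Of the 178 genes, 70.8% were below 0 on type B by another probe set, against at most 68.5% in 10000 random sets matched on type B signal. Genes are not independent, and the shared probe sets, with 8 of 11 against 67 of 100, held no clear excess. That error is therefore not excluded as the whole cause. A smaller difference enlarged on type A by noise and a stronger 3' bias of the IFN-α2b RNA remain open, as the 3' to 5' ratio of 2 controls was higher with IFN-α2b by a mean of 0.65 on the log2 scale on type B and 0.51 on type A, with GAPDH higher by more on type A and beta-actin on type B. A lowering of some of these transcripts by interferon also remains open, since 11.8% were at least 2-fold lower on type B, against 6.11% of all genes, just under the 2 times set as the mark for it. With quantile normalization (13.5% and 6.38%), median centring (11.5% and 5.67%), loess correction (11.5% and 5.71%) and the 75th percentile floor (10% and 3.36%) that mark was passed, and with the 5 other alternatives it was not.

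The metallothioneins were higher as a family on array type A, with log2 ratios from 1.02 to 3.29 over 9 probe sets. Error of the single arrays that is separate for each gene is argued against as the whole cause, because the median log2 ratio of 2.27 over 6 genes, a list fixed before the data were seen, lay above all 10000 random lists. An error common to probe sets that share probes is not excluded by this. Cross-hybridization of 1 raised member to the probe sets of the others remains open, because 0 of the 9 have an ID other than the kind given to probe sets that share probes between genes. A higher level of several family members under interferon was not tested.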

How the results depend on the processing

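Scaling on hybridization controls was chosen after seeing the data. With 1 array per condition and type, no leave-one-out or test was possible. No paired analysis was run, as each group holds 1 array and the labels do not say whether the A and B arrays share RNA. Counts at 2-fold stayed within 1.5 times of the main count with median centring, quantile normalization, loess correction and the median over probe sets. They moved with the floor, which sets how many dim genes are tested. With the floor at the 25th percentile, 1865 genes were higher and 1173 lower on type A, and 1334 and 1242 on type B. At the 75th percentile, the counts were 260 and 256 on type A and 176 and 147 on type B, and with no floor and log2(value + 16), 2045 and 1268, and 1504 and 1396. Without shared probe sets, type A gave 387 and 356, over fewer genes. Scaling on hybridization controls gave 342 and 1290 on type A, and 201 and 1434 on type B. At 1.5-fold, 1547 and 1453 genes differed on type A and 1179 and 1297 on type B, and at 3-fold 206 and 104, and 139 and 64.

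The share of genes 2-fold higher on type A that were so on type B was 27.7% with the 25th percentile floor, 53.4% with the 75th and 25.2% with none, where 15.3%, 6.28% and 14.98% of all genes were so on type B. For lower genes it ranged from 7.25% with the median over probe sets, against 4.91% of all genes, to 36.1% with scaling on hybridization controls, against 23.9%. It was more than 2 times that of all genes with quantile normalization, median centring, loess correction and the 75th percentile floor (10% against 3.36%). Scaling on hybridization controls lowers type A ratios by 0.38, less than the limit of 0.42 set for list medians. A median could thus cross 0 under it and stay within the limit. NF-kB targets (0.29 to -0.06) and MHC class II genes (0.35 to -0.03) did so. Of 257 list medians under alternatives, 235 lay within 0.42 of the main median. The others follow as log2 ratios. Antiviral genes had 3.14 with the 75th percentile floor. With the 25th percentile floor, chemokines had 3.81, nucleic acid sensors 1.17, T cell markers 0.40, B cell markers 0.028, natural killer cell markers 1.13, red cell markers 0.84 and dendritic cell markers 0.58. With no floor, T cell markers had 0.43, B cell markers 0.023, natural killer cell markers 1.23, red cell markers 0.88, neutrophil markers 0.61 and dendritic cell markers 0.55. Without shared probe sets, chemokines had 4.63, dendritic cell maturation genes 0.70, guanylate-binding and related genes 3.68 and T cell markers 0.29. Scaling on hybridization controls gave 0.24 for nucleic acid sensors and 0.12 for B cell markers. Platelet markers turned to -0.58 with the 25th percentile floor and -1.05 with none, and CFB to -0.10 without shared probe sets. The cause was not tested. Of 58 named genes at least 2-fold higher, 49 were so when scaled on hybridization controls. That scaling lowers the ratios, so the 22 named lower genes could not be lost under it. With the 75th percentile floor, 46 of 50 measured higher genes and 17 of 22 lower ones stayed at 2-fold. Without shared probe sets, 39 of 41 and 13 of 14 did. The lists of metallothioneins, cell cycle genes and several cell types gave no value in some settings, where fewer than 3 members were left. Across the alternatives, the antiviral, chemokine and guanylate-binding lists stayed at percentile 100 of random lists and class I presentation at 99.94 or more, while the cholesterol list ranged from 2.16 to 45.3 and NF-kB targets from 35.8 to 99.7.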

Other observations

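Genes outside the 25 lists that were at least 2-fold different in the same direction on both array types, by different probe sets, numbered 43 higher and 21 lower. Among genes measured on both types, 41.4% of those at least 2-fold higher on type A were so on type B, against 7.82% of all. For lower genes the shares were 11.8% and 6.11%. Some of the 21 can thus be there without a shared difference. The 43 higher and 21 lower genes were selected after their values were seen. Among the higher were PML, the scaffold of nuclear bodies (log2 ratio at least 4.25 on type A and 3.92 on type B), SAMHD1, which depletes nucleotides and restricts retroviruses (2.29 and 1.80), SLAMF7, a leukocyte surface receptor (2.36 and 1.89), the prothrombinase FGL2 (1.99 and 2.16), heparanase HPSE (2.20 and 1.64), the ubiquitin ligase TRIM25, which acts on RNA sensors (1.84 and 1.92), the endosomal chaperone of Toll-like receptors UNC93B1 (at least 2.06 and 1.58), and EDN1, the vasoconstrictor endothelin (1.39 and 1.97).

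Among the 21 lower on both types were the tetraspanin CD9 (-2.16 and at most -1.39), the sialyltransferase ST3GAL1 (at most -2.52 and -1.20), the kinase BMP2K (-1.95 and -1.57), the amino acid transporter SLC38A1 (-1.89 and at most -1.53), AGO1 of the microRNA pathway (-1.62 and -1.81), the G protein subunit GNA12 (-1.29 and -1.61), the tRNA exporter XPOT (-1.35 and -1.67) and the transporter ABCC3 (-1.29 and -1.23).

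VEGFA, an angiogenic factor induced by low oxygen, was 6.41-fold lower with IFN-α2b, with log2 ratios from -2.68 to -0.65 over 4 probe sets. A hypothesis drawn from it was that hypoxia-responsive genes were lower as a group. A list of 24 such genes, 1 of them (SLC2A1) also in the glycolysis list, was written before its median was computed, and without VEGFA 20 were measured, 4 of them at least 2-fold lower and 2 higher. Their median log2 ratio was -0.31, at percentile 3.15 of random lists, short of the 2.5 set beforehand, and the percentile ranged from 2.45 to 11.2 across the alternatives, so the hypothesis remains undecided. DDIT4 was 3.56-fold, KDM3A 2.59-fold, PLIN2 2.36-fold and EGLN1 at least 2.21-fold lower, while CA12 was 2.32-fold and HILPDA at least 2.14-fold higher. The other probe set of PLIN2 had a log2 ratio of 1.75, and those of CA12 went down to -0.28.

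Measured probe sets that name no single gene numbered 1612 on type A, of which 112 were at least 2-fold higher and 92 lower, and 4014 on type B, of which 284 were higher and 191 lower.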
